A study of Mus musculus with 25 samples.

How the data were processed

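Total RNA of mouse intestine had been hybridised as biotin-labelled samples to Illumina bead arrays, on which each probe is read on many beads. The groups and replicate numbers were taken from the sample titles, and IL10 knockout and IL10 interaction refer to arrays with that label. Loops had been made by resecting 2.5 cm of ileum 3 cm from the ileocecal valve, and tissue was taken after 5 weeks. The description numbers of 4 samples differ from those in their titles. An array code in each sample description runs in a series MW for 19 arrays and a series MX for 6, and all TLR4 knockout arrays are MX. No slide was given, so codes were also grouped in runs of 8, which does not establish that such arrays shared a slide.

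The intensity values are average bead signals per probe on a linear scale, as deposited by the authors in a table without background subtraction or normalization, with 25697 probes. Each came with a detection p-value per probe and array, as deposited, and with a bead number. The software that made the intensity values and each p-value is not given in the sources used here. The authors also deposited processed log2 values of 17612 of the probes, and the submitters' processing notes name limma without a version. Set against the present normalization, each of the 25 columns of log2 values correlated best with its own array (lowest r 0.99999, largest difference 0.0951, median difference 0.0135), so their scale is known and the authors' filter is not. Their column medians were all close to 6.02. The 8085 probes left out were detected on no array, and so were 563 of those kept. There were 0 columns of per-sample values without a sample, and 0 pairs of arrays with identical signals.

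Signals were background-corrected by normexp with parameters inferred from the detection p-values, given an offset of 16, quantile-normalized over all arrays and put on a log2 scale (neqc in limma 3.58.1, statmod 1.5.0, R 4.3.3). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Bead numbers were not used as weights. Detection at p under 0.05 on at least 3 arrays kept 15318 probes. Of several probes of a gene, the one with the highest mean normalized log2 value stood for it, which gave 11227 genes, 2896 of them with more than 1 such probe. Where another probe of a named gene differed by more than 1 log2 unit, its value is given with the gene in comparisons of genotypes. Probes carried the names of the array's design. Of these, 23788 were updated by Entrez gene number, 1148 by accession and 98 through an older symbol, 99 symbols were unchanged and 564 kept the file's name. The reference table of assembly GRCm38.p6 served only for names and for gene neighbourhood, since no probe position or genome build is given in the sources used here.

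Between 47.2 and 53.0% of probes were detected per array. The lowest signal lay between 80.9 and 94.5, the median between 101.0 and 130.2 and the ratio of the 95th percentile to the median between 9.36 and 16.3. The first 2 principal components held 35.4 and 21% of the variance.

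Before the data were examined, the comparisons, the alternatives, the gene lists and the rule for named genes were fixed. A linear model with a mean per group was fitted to all arrays in limma, with moderated errors (17 residual and 3.92 prior degrees of freedom) and Benjamini-Hochberg adjusted p-values over genes. A gene passed at an adjusted p under 0.05, and "rose", "fell" and "changed" are used of such genes only. Named genes were the 10 largest rises and 10 largest falls among passing genes whose arrays did not overlap between the groups (5 and 5 for comparisons of genotypes and for interactions, the latter without the overlap condition), up to 4 passing members of each fixed list with the largest change (where none passed, the 2 with the smallest p), and Tlr4 and Il10, of which the report gives about 20 to 30 in the larger comparisons. A probe with a detection p of 0.05 or more on every array of a group has only a bound there. Its fold is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own, on normalized log2 values.

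The 29 lists held 518 symbols, 402 of them tested. They cover bile acids, digestion, large intestinal epithelium, TLR4 and NF-kB signalling, cytokines, antimicrobial defence, mucin sulfation, cell cycle, stem cells and Wnt targets, MHC class II, interferon response, fatty acid oxidation, cholesterol synthesis, xenobiotic metabolism and tight junctions, and Paneth, goblet, enteroendocrine, T, B and plasma, macrophage, neutrophil, mast, smooth muscle, fibroblast, endothelial, enteric neuron and glia, adipocyte and pancreatic acinar cells. The interferon and cytokine lists share 2 genes. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, with an estimated correlation and fry beside it. Camera compares a list with the other genes, and fry does not. The position of an array between sham ileum and sham cecum is the least-squares slope of its difference from mean sham ileum on the cecum minus ileum difference, over genes past adjusted p 0.05 and 1 log2 unit between the sham tissues, and was tested by exact two-sided permutation. For splits of the arrays in an interaction, the filling effect of an additive model of genotype and loop was subtracted first. Sham arrays left out of the axis in turn lay between -0.0012 and 0.0323 for ileum and between 0.958 and 0.997 for cecum.

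The model was tested on simulated data with 200 of 11227 genes changed. Noise was drawn for each gene independently at its residual SD, without correlation between genes and without effects of run, code series or signal ratio. The shares below hold for such data and may be too favourable for the real arrays. For self-filling against self-emptying wild type loops it recovered 22% of 50 genes changed by 0.5 log2 units, 74% at 1, 98% at 2 and 100% at 4. For self-filling against sham ileum these shares were 26, 80, 100 and 100%, for the TLR4 knockout loops 12, 70, 100 and 100%, for the TLR4 interaction 6, 54, 90 and 100%, and for the IL10 interaction 10, 50, 92 and 100%. Of 11027 unchanged genes 7, 7, 6, 4 and 8 were called in these settings, in the order wild type loops, sham ileum, TLR4 knockout loops, TLR4 interaction and IL10 interaction. Alternatives covered the background correction, the authors' processed values, the detection filter, the choice of probe, the samples in the fit, the error model, array weights, the replicate number as a block by title or by description, the threshold, separate normalization of the code series and each array left out. Runs of codes as a block, the signal ratio as a covariate, and fits without single doubted arrays were added after seeing the data.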

Results

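Gene expression was measured on 25 Illumina bead arrays of mouse intestine in 8 groups. Segments of ileum had been rebuilt as surgical loops 5 weeks earlier. A self-filling loop is placed so that intestinal content collects and stands in it, and a self-emptying loop has the same surgery but drains. Wild type mice gave sham-operated ileum (n = 3), sham-operated cecum (n = 3), self-emptying loops (n = 4) and self-filling loops (n = 3). Mice labelled as knockouts for IL10, a cytokine that restrains inflammation, or for TLR4, the receptor for bacterial lipopolysaccharide, gave 3 self-emptying and 3 self-filling loops each. Between 12123 and 13627 of the 25697 probes were detected per array, behind a median of 33 to 39 beads per probe, and the number of arrays limits the precision. Arrays of 1 group correlated with r between 0.968 and 0.992 over the genes tested. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Changes are log2 fold changes ± SE, with adjusted p over the 11227 genes tested.

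The targeted genes were read first, as a check of the labels. The Tlr4 probe lay at a normalized log2 intensity of 4.40 ± 0.15 (SD, n = 3) in TLR4 knockout self-filling loops and 4.60 ± 0.16 (SD, n = 3) in TLR4 knockout self-emptying loops, with detection on 1 of those 6 arrays. In wild type it was detected on every array and lay at 5.40 ± 0.23 (SD, n = 3) in self-filling loops, 5.21 ± 0.28 (SD, n = 4) in self-emptying loops, 4.99 ± 0.13 (SD, n = 3) in sham ileum and 6.88 ± 0.39 (SD, n = 3) in sham cecum. In loops labelled IL10 knockout Tlr4 lay at 5.95 ± 0.27 (SD, n = 3) with self-filling and 5.69 ± 0.33 (SD, n = 3) with self-emptying. The TLR4 knockout level was at least 1.5-fold below wild type in self-filling loops (adjusted p = 0.00392), and the difference in self-emptying loops did not pass (-0.62 ± 0.19, adjusted p = 0.0598). The other Tlr4 probe was detected on 0 of the 25 arrays by its detection p. As Il10 was detected on no wild type array, a loss could not show, and the Il10 probe was higher with the knockout label. It was detected on all 6 arrays labelled IL10 knockout, at 7.34 ± 0.10 (SD, n = 3) in self-filling and 6.65 ± 1.01 (SD, n = 3) in self-emptying loops, and on none of the other 19, whose group means ran from 4.31 to 4.56. Against wild type it was at least 5.48-fold higher in self-filling loops (adjusted p = 9.68e-07) and at least 3.68-fold higher in self-emptying loops (adjusted p = 2.87e-05). A probe outside the deleted part of a gene checks nothing about a deletion, and the probe's position in Il10 is not known here. Every direction drawn from these arrays rests on the label, and IL10 knockout stands for arrays so labelled.

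The comparison of wild type self-filling loops with sham ileum covers loop surgery and standing content together. Among the largest rises were the secretoglobin Scgb2b7 (4.76 ± 0.80, adjusted p = 0.000839), the goblet cell protein Retnlb (3.82 ± 1.10, adjusted p = 0.0206), the acute phase glycoprotein Lrg1 (3.35 ± 0.44, adjusted p = 0.000107), Gprc5a (2.93 ± 0.54), the TWEAK receptor Tnfrsf12a (2.89 ± 0.59) and the peptide precursor Cartpt (2.81 ± 0.47). Among the largest falls, the adipocyte protease Cfd changed by -5.49 ± 1.58 (adjusted p = 0.0203), Car3 was at least 23-fold lower (adjusted p = 0.0175), the desaturase Scd1 changed by -4.30 ± 1.36 and the glucose-6-phosphatase G6pc by -3.41 ± 0.67. In all, 2212 genes passed, 1177 higher and 1035 lower, and 584 of them differed by at least 1 log2 unit.

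The fixed lists describe these genes by function and cell type. Among genes of small intestinal digestion and absorption, 7 of 23 measured members fell and 2 rose, and 12 fell when adjusted over the list alone. Among them were the brush border protease Mep1a (-1.81 ± 0.40) and the peptide transporter Slc15a1 (-1.47 ± 0.37). Of the bile acid list 1 of 6 fell, the bile acid exporter subunit Slc51b (-0.99 ± 0.29), and of the Paneth cell list 1 of 13 (4 adjusted over the list alone), the defensin Defa21 (-1.55 ± 0.45). Interferon-response genes fell in 7 of 24 cases (14 adjusted over the list alone), with the antiviral Rsad2 at -2.92 ± 0.38, Oasl2 at -2.11 ± 0.42 and Ifit3 at -1.95 ± 0.61. Antigen presentation by MHC class II fell in 7 of 12 genes (7 adjusted over the list alone), including H2-Eb1 (-1.54 ± 0.35) and H2-Ab1 (-1.30 ± 0.29). Markers of other cell types moved in the same samples. T cell genes fell in 5 of 11 cases, with Cd3g at -2.09 ± 0.47 and Cd3e at -1.46 ± 0.35, macrophage genes in 6 of 13, with the complement gene C1qb at -1.63 ± 0.49, and smooth muscle genes in 3 of 14, with Myh11 at -1.94 ± 0.61 and Flna at -1.89 ± 0.48. Endothelial genes fell in 3 of 10 cases and adipocyte genes in 4 of 7, with Adipoq at -4.06 ± 1.34 and Plin4 at -2.32 ± 0.69. The cell cycle list rose in 3 of 20 members (3 adjusted over the list alone), among them the mitotic kinases Plk1 (0.91 ± 0.26) and Aurka (0.84 ± 0.25). Adjusted over the list alone, the falls numbered 1 for bile acids, 5 for T cells, 6 for macrophages, 3 for smooth muscle, 5 for endothelium and 5 for adipocytes. All these lists passed camera with the preset correlation, and none held with an estimated one, where adjusted p = 0.551 for smooth muscle and adjusted p = 0.506 for each of the others.

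Single members of lists that did not pass as a set also changed. Goblet cell genes rose in 4 of 14 cases (5 adjusted over the list alone, camera adjusted p = 0.0779), including the disulfide isomerase Agr2 (1.35 ± 0.30), the transcription factor Spdef (1.15 ± 0.37) and the kallikrein Klk1 (1.14 ± 0.29). The large intestinal list had 2 of 19 members that rose, the water channel Aqp4 (1.79 ± 0.34) and the carbonic anhydrase Car4 (1.17 ± 0.31), and 1 that fell, both numbers unchanged when adjusted over the list alone (camera adjusted p = 0.621). The scavenger receptor Dmbt1 rose (1.21 ± 0.22) and so did the IL-1 antagonist Il1rn (2.08 ± 0.47). The T cell chemokine Ccl5 fell (-2.23 ± 0.58), as did the xenobiotic enzymes Cyp3a25 (-3.03 ± 0.96) and Cyp2d26 (-3.0 ± 0.50). Tlr4 itself did not pass (0.42 ± 0.20, adjusted p = 0.149). With the signal ratio as a covariate the smooth muscle (adjusted p = 0.101) and endothelial lists (adjusted p = 0.119) were no longer called. The count was 3610 with array weights, 905 without self-filling replicate 3, 993 without sham ileum replicate 2 and 1461 without sham ileum replicate 3.

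The self-emptying loop against sham ileum asks what the surgery does without stasis. A single gene passed in limma, Spsb4, which belongs to a family of ubiquitin ligase adaptors and changed by -1.45 ± 0.20 (adjusted p = 0.00533), and 883 genes had an unadjusted p under 0.05. No member of any list passed over all genes. As sets, 4 lists lay lower in camera with small medians, the bile acid genes at -0.39, enteroendocrine genes at -0.42, interferon genes at -0.27 and macrophage genes at -0.29. Adjusted over the list alone, 1 of 6 bile acid and 2 of 12 enteroendocrine genes fell and none of the others. None of the calls held with an estimated correlation (adjusted p = 0.655 for the bile acid and enteroendocrine lists and adjusted p = 0.914 for the others). The enteroendocrine call ended without the 2 self-emptying arrays of codes 9 to 16 (adjusted p = 0.116) and the macrophage call without background correction (adjusted p = 0.0843). Array weights gave 25 genes, a fit of these groups alone 9, and 7 other settings 2 to 4. No gene passed without sham ileum replicate 1 or without sham ileum replicate 2, where limma gave 0, and 2 passed without self-emptying replicate 1.

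Self-filling against self-emptying loops compares stasis at equal surgery in wild type. Of the genes with the largest rises, Scgb2b7 (3.65 ± 0.74, adjusted p = 0.00529), the surface protein Ly6d (3.14 ± 0.67, adjusted p = 0.00688), Lrg1 (2.79 ± 0.41, adjusted p = 0.000487), Gprc5a (2.66 ± 0.50), the aldo-keto reductase Akr1b8 (2.55 ± 0.33) and Cartpt (2.52 ± 0.44) rose. Cfd (-5.44 ± 1.48, adjusted p = 0.0233) and the lipoprotein lipase Lpl (-3.17 ± 0.88) fell, Car3 was at least 18.8-fold and the cytochrome Cyp2e1 at least 8.01-fold lower, and the intestinal sphingomyelinase Enpp7 fell (-2.78 ± 0.56). In limma 1295 genes passed, 667 higher and 628 lower, with 352 differing by at least 1 log2 unit.

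Large intestinal genes rose in 4 of 19 cases in this comparison, and none fell. They were Aqp4 (1.52 ± 0.32), the cortisol-inactivating enzyme Hsd11b2 (1.12 ± 0.36), Car4 (1.07 ± 0.29) and the keratin Krt20 (0.44 ± 0.14), while the list as a set did not pass (camera adjusted p = 0.316). Goblet cell genes rose in 4 of 14 cases, with Klk1 at 1.48 ± 0.27, Agr2 at 1.24 ± 0.28 and the membrane mucin Muc4 at 0.98 ± 0.32 (camera adjusted p = 0.0623). The cell cycle list rose in 3 of 20 members, including the ribonucleotide reductase subunit Rrm2 (1.14 ± 0.30) and Plk1 (0.85 ± 0.24). MHC class II genes fell in 5 of 12 cases, with H2-Eb1 at -1.61 ± 0.33 and H2-Ab1 at -1.38 ± 0.27, and interferon genes in 3 of 24, among them Rsad2 (-1.75 ± 0.35) and Oasl2 (-1.53 ± 0.39). Digestive genes fell in 3 of 23 cases and rose in 1, with Mep1a at -1.44 ± 0.37 and Slc15a1 at -1.24 ± 0.34. Paneth cell genes fell in 3 of 13, including the lipase-related Pnliprp2 (-1.71 ± 0.46) and Defa21 (-1.38 ± 0.42). Markers of other cells fell in the same arrays, with T cell genes in 4 of 11 cases (Cd3g -1.84 ± 0.44, Cd3e -1.39 ± 0.33), endothelial genes in 5 of 10 (Cldn5 -1.22 ± 0.36, Pecam1 -1.10 ± 0.30) and adipocyte genes in 2 of 7 (Cfd above and Plin4 -2.25 ± 0.65). No macrophage gene and no smooth muscle gene passed, though both lists passed camera with medians of -0.67 and -0.67. None of these 10 camera calls held with an estimated correlation (adjusted p = 0.66 for macrophages, adjusted p = 0.672 for smooth muscle and adjusted p = 0.623 for the others). Adjusted over the list alone, the falls numbered 6 for digestion and MHC class II, 5 for Paneth cells, T cells and adipocytes, 7 for endothelium, 3 for interferon genes, 2 for macrophages and 0 for smooth muscle, and the rises 3 for the cell cycle, 6 for goblet cells and 4 for the large intestine. Without the 2 self-emptying arrays of codes 9 to 16, the macrophage (adjusted p = 0.439) and adipocyte lists (adjusted p = 0.0787) were no longer called. With runs as a block the macrophage (adjusted p = 0.122) and smooth muscle calls (adjusted p = 0.0622) ended. The signal ratio as a covariate ended those of the cell cycle (adjusted p = 0.168), macrophages (adjusted p = 0.55), smooth muscle (adjusted p = 0.578) and adipocytes (adjusted p = 0.0648).

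Genes that sense bacterial products were mostly not past the test in the wild type filled loop. The lipopolysaccharide co-receptor Cd14 rose (0.75 ± 0.22, adjusted p = 0.0336), the NF-kB subunit Relb fell (-1.14 ± 0.25), Tlr4 did not pass (0.19 ± 0.19, adjusted p = 0.54), and the TLR4 and NF-kB list did not pass (1 of 22 rose, 1 fell, camera adjusted p = 0.0511). Dmbt1 rose (1.17 ± 0.20) and Cyp2d26 fell (-2.28 ± 0.46). The 3 self-filling arrays had array codes 1 to 8 and 17 to 24, whereas 2 of the 4 self-emptying arrays, replicates 2 and 3, had codes 9 to 16, a run with a lower ratio of the 95th percentile to the median signal (median 10.8 over its 6 arrays, against 15.3 and 14 in the other runs). The count was 2125 with array weights, 714 with runs of 8 codes as a block and 329 with that ratio as a covariate. It was 86 without these 2 arrays, which leaves the runs that hold both loop types, 527 without replicate 2 and 696 without replicate 3 of the self-emptying loop, and 356 and 619 without self-filling replicates 3 and 1. Each run with both loop types held 1 self-emptying array, and no count was made within a single run.

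Sham cecum against sham ileum gave the direction from small to large intestine. Ileal genes of digestion, bile acid handling and Paneth cell defence were far lower in the cecum. Apolipoprotein Apoa1 lay lower by -9.41 ± 0.26 (adjusted p = 9.65e-18), the disaccharidase Sis by -9.0 ± 0.19 and the aminopeptidase Anpep by -8.03 ± 0.47, and 22 of 23 digestive genes fell. The bile acid genes fell in 6 of 6 cases, with the transporter subunits Slc51a (-8.25 ± 0.36) and Slc51b (-3.78 ± 0.29) and the binding protein Fabp6 (-6.54 ± 0.18). Paneth cell genes fell in 13 of 13, with the defensins Defa21 (-9.31 ± 0.45), Defa26 (-9.27 ± 0.18) and Defa5 (-9.17 ± 0.16). Large intestinal genes rose in 17 of 19 cases and fell in 1, including Sycn (8.90 ± 0.32), the water channel Aqp8 (7.98 ± 0.18), the proton pump Atp12a (at least 372-fold) and the hormone Insl5 (at least 109-fold). The numbers were the same adjusted over the list alone. These 4 lists held with an estimated correlation (adjusted p = 0.0162 for digestion, adjusted p = 0.0101 for bile acids, adjusted p = 3.75e-05 for Paneth cells and adjusted p = 2.87e-07 for the large intestine).

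Further genes separated cecum from ileum. Antimicrobial genes rose in 6 of 19 cases and fell in 5, with the same numbers adjusted over the list alone (camera adjusted p = 0.846). The lectins Reg3g (-8.45 ± 0.33) and Reg3b (-6.09 ± 0.14) and the crypt gene Olfm4 (at least 94.3-fold) were lower in cecum. The carbonic anhydrase Car2 (7.82 ± 0.16), the protease inhibitor Wfdc2 (6.80 ± 0.50), the glycosyltransferase B3gnt7 (4.38 ± 0.37), Il1rn (3.82 ± 0.47) and Klk1 (2.92 ± 0.29) were higher. The cecum also had higher Tlr4 (1.89 ± 0.20, adjusted p = 2.64e-07), Cd14 (2.13 ± 0.24) and Tlr2 (1.47 ± 0.19). MHC class II genes fell in 7 of 12 cases, with H2-DMa at -2.86 ± 0.34 and Cd74 at -2.11 ± 0.37, enteroendocrine genes in 5 of 12, with neurotensin Nts at -4.62 ± 0.43 and secretin Sct at -4.24 ± 0.32, interferon genes in 9 of 24, and cholesterol synthesis genes in 9 of 14, with Cyp51 at -1.74 ± 0.17. Goblet cell genes rose in 5 of 14 cases and mucin sulfation genes in 9 of 19. With adjustment over the list alone 7 enteroendocrine genes fell and 6 goblet cell genes rose, and the other 4 numbers did not change. Those 6 lists lost their call with an estimated correlation, where adjusted p = 0.0902 for cholesterol synthesis, adjusted p = 0.117 for mucin sulfation and adjusted p = 0.453 for the rest, and the goblet cell list with the signal ratio as a covariate (adjusted p = 0.0588). In all 3121 genes passed, 1823 higher and 1298 lower.

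The question whether loops move toward large intestine was put to each array with 1190 genes, on a scale where sham ileum is 0 and sham cecum 1. These genes were chosen by the difference between the sham tissues. Their error estimates and the detection filter also drew on the loop arrays, and the choice was not repeated for exchanged labels. Wild type self-filling loops lay at 0.137 ± 0.0307 (SD, n = 3) and self-emptying loops at 0.0397 ± 0.0269 (SD, n = 4), all 3 above all 4. In the runs that held both, the 3 self-filling arrays lay above the self-emptying arrays at 0.0344 and 0.0147. The difference of 0.0976 had p = 0.0286 in an exact two-sided permutation test of 35 splits, the smallest such a design can give, and adjusted p = 0.0857 over the 3 genotypes. Arrays labelled IL10 knockout lay at 0.216 ± 0.0365 (SD, n = 3) with self-filling and 0.141 ± 0.0489 (SD, n = 3) with self-emptying, a difference of 0.0752 with p = 0.2 by the exact permutation test (adjusted p = 0.3). TLR4 knockout loops lay at 0.138 ± 0.107 (SD, n = 3) and 0.0583 ± 0.0415 (SD, n = 3), a difference of 0.0801 with p = 0.4 by the exact permutation test (adjusted p = 0.4), which is 0.0195 without self-filling replicate 2. With 3 arrays against 3 the test cannot go below 0.1. Over the 3 genotypes together, with labels exchanged within genotype, the mean difference was 0.0843 with p = 0.0015 in the exact permutation test of 14000 combinations. The shifts of the knockouts did not differ detectably from that of wild type by permutation (p = 0.729 for IL10 and p = 0.879 for TLR4). Across all tested genes the filling effect correlated weakly with the cecum against ileum difference, with Pearson r = 0.208 and Spearman rho = 0.16 in wild type, 0.145 and 0.0564 in loops labelled IL10 knockout and 0.241 and 0.162 in TLR4 knockout loops. Genes are not independent replicates, and no p is given for these 3 correlations. Of the genes called between wild type loops, 216 rose with filling and were higher in cecum and 158 were lower in both, against 108 and 72.6 for independent lists, and 56 and 68 went opposite ways.

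**Figure D1:**
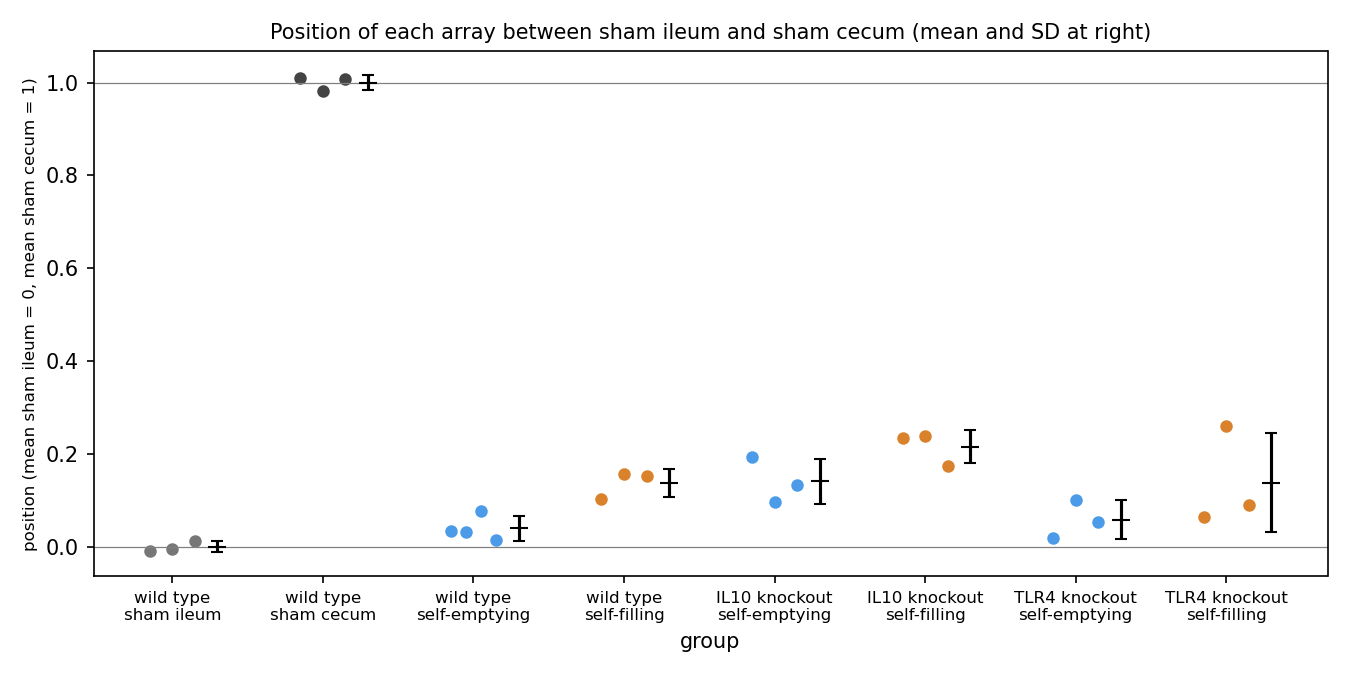
Position of each of the 25 arrays between sham ileum (0) and sham cecum (1) on the vertical axis, a unitless scale, by group on the horizontal axis. Points are arrays, and the bars at their right are the group mean and SD. Wild type self-filling loops sit between 0.102 and 0.158 and wild type self-emptying loops between 0.0147 and 0.0779.

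In loops labelled IL10 knockout, self-filling was compared with self-emptying. The iron-binding Lcn2 (4.87 ± 0.55, adjusted p = 2.32e-05), the chitinase-like Chil3 (4.47 ± 0.56, adjusted p = 9.41e-05), the B cell chemokine Cxcl13 (4.14 ± 1.03, adjusted p = 0.0278), the calprotectin subunits S100a8 (3.83 ± 0.87) and S100a9 (2.87 ± 0.73), haptoglobin Hp (3.74 ± 0.74), the acute phase protein Saa3 (3.50 ± 0.61), the formyl peptide receptor Fpr2 (2.96 ± 0.45) and Cartpt (2.73 ± 0.47) rose. The gasdermin Gsdmc2 (-4.26 ± 0.99), the arginase Arg2 (-2.76 ± 0.35) and the crypt genes Axin2 (-1.06 ± 0.22) and Sox9 (-0.70 ± 0.18) fell, and the neuropeptide Nmu was at least 5.37-fold lower. In all 462 genes passed, 215 higher and 247 lower.

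By list, inflammatory cytokines rose in 7 of 18 cases and fell in none (8 rose adjusted over the list alone), with Cxcl10 at 2.49 ± 0.37, Cxcl1 at 1.99 ± 0.54 and Cxcl9 at 1.92 ± 0.46. Neutrophil genes rose in 3 of 8 (3 adjusted over the list alone), with lactoferrin Ltf at 1.56 ± 0.31, and macrophage genes in 1 of 13 (3 adjusted over the list alone), Cd68 (1.41 ± 0.40). Paneth cell genes fell in 7 of 13 cases (8 adjusted over the list alone), with Pnliprp2 at -3.55 ± 0.50, the antimicrobial Ang4 at -3.28 ± 0.64, colipase Clps at -2.77 ± 0.43 and Defa21 at -2.40 ± 0.45. The stem cell and Wnt target list fell in 2 of 14 (5 adjusted over the list alone) and no cholesterol synthesis gene passed, though both lists lay lower in camera with medians of -0.33 and -0.28. None of the 6 calls held with an estimated correlation (adjusted p = 0.213 for cytokines and Paneth cells, adjusted p = 0.422 for neutrophils and stem cells, adjusted p = 0.607 for cholesterol synthesis and adjusted p = 0.73 for macrophages). Of the TLR4 and NF-kB list 4 of 22 rose (6 adjusted over the list alone) without the list passing (camera adjusted p = 0.0685). They were Lbp (1.36 ± 0.36), the NF-kB inhibitor Nfkbia (1.31 ± 0.27), Cd14 (0.91 ± 0.24) and Tlr2 (0.69 ± 0.19). Of the large intestinal list 2 of 19 rose, Aqp4 (1.75 ± 0.34) and Hsd11b2 (1.49 ± 0.39). The count was 104 without self-filling replicate 1, 759 without self-filling replicate 3, 224 and 247 without self-emptying replicates 2 and 1, and 5 when only these 6 arrays entered the fit.

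In TLR4 knockout loops 9 genes passed between filling and emptying, and 1014 had an unadjusted p under 0.05. Cartpt (2.73 ± 0.47, adjusted p = 0.0163), Lrg1 (2.34 ± 0.44, adjusted p = 0.0323), the neutrophil surface protein Cd177 (1.76 ± 0.30, adjusted p = 0.0163) and Dmbt1 (1.43 ± 0.22, adjusted p = 0.00995) rose. The carboxylesterase Ces1c (-1.30 ± 0.20), the scramblase Plscr4 (-1.22 ± 0.21), Rnf32 (-0.76 ± 0.14) and 1700057G04Rik (-1.70 ± 0.29) fell, and the cytochrome Cyp2b10 was at least 1.65-fold lower. All 4 that rose had also risen in wild type, against 0.238 for independent lists, and 2 of the 5 that fell had fallen there, against 0.28. Of the 1295 genes called in wild type, 1180 (91.1%) had a fold change of the same sign in TLR4 knockout loops, most without passing there, with a slope of 0.448, against 891 (68.8%) and a slope of 0.27 in loops labelled IL10 knockout. These genes were chosen by their wild type change, which alone lowers such slopes, so the slopes do not measure a weaker response. Genotypes share no array here, but the error of each gene was estimated over all arrays, so the lists are not fully independent. The numbers for independent lists are therefore a rough baseline, here and in the other overlaps of calls.

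As sets, TLR4 knockout loops differed in 11 lists by camera with the preset correlation, and none of these calls held with an estimated one. Almost no member passed over all genes. Lower with filling were xenobiotic enzymes (median -0.70, 7 of 17 fell adjusted over the list alone, 1 over all genes), MHC class II genes (-0.95, 6 of 12 adjusted over the list alone), digestive genes (-0.41, 3 of 23 adjusted over the list alone), Paneth cell genes (-0.31), T cell genes (-0.41) and adipocyte genes (-0.76). Higher were interferon genes (0.50, 5 of 24 adjusted over the list alone), cell cycle genes (0.39), neutrophil genes (0.38), fibroblast genes (0.61) and antimicrobial genes (0.13, with 1 of 19 past the test over all genes). With an estimated correlation the values were as follows (adjusted p = 0.179 for xenobiotic enzymes, adjusted p = 0.234 for MHC class II, adjusted p = 0.377 for Paneth cells, adjusted p = 0.526 for adipocytes, adjusted p = 0.553 for the cell cycle, adjusted p = 0.598 for T cells and fibroblasts and adjusted p = 0.368 for the rest). Without self-filling replicate 2 the digestive (adjusted p = 0.191), Paneth cell (adjusted p = 0.0624), cell cycle (adjusted p = 0.0843), T cell (adjusted p = 0.219), neutrophil (adjusted p = 0.0639) and fibroblast lists (adjusted p = 0.0746) were no longer called. The neutrophil call also ended without background correction (adjusted p = 0.0781). The gene count was 32 and 30 with replicate numbers of titles and of descriptions as a block, 19 with array weights, 15 without background correction, and 14 with normexp at an offset of 50 or with the stricter detection filter. It was 3 without self-filling replicate 2, 37 without self-filling replicate 1, 14 without self-filling replicate 3, 0 in limma without self-emptying replicate 1 and 0 when only these 6 arrays entered the fit.

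**Figure D2:**
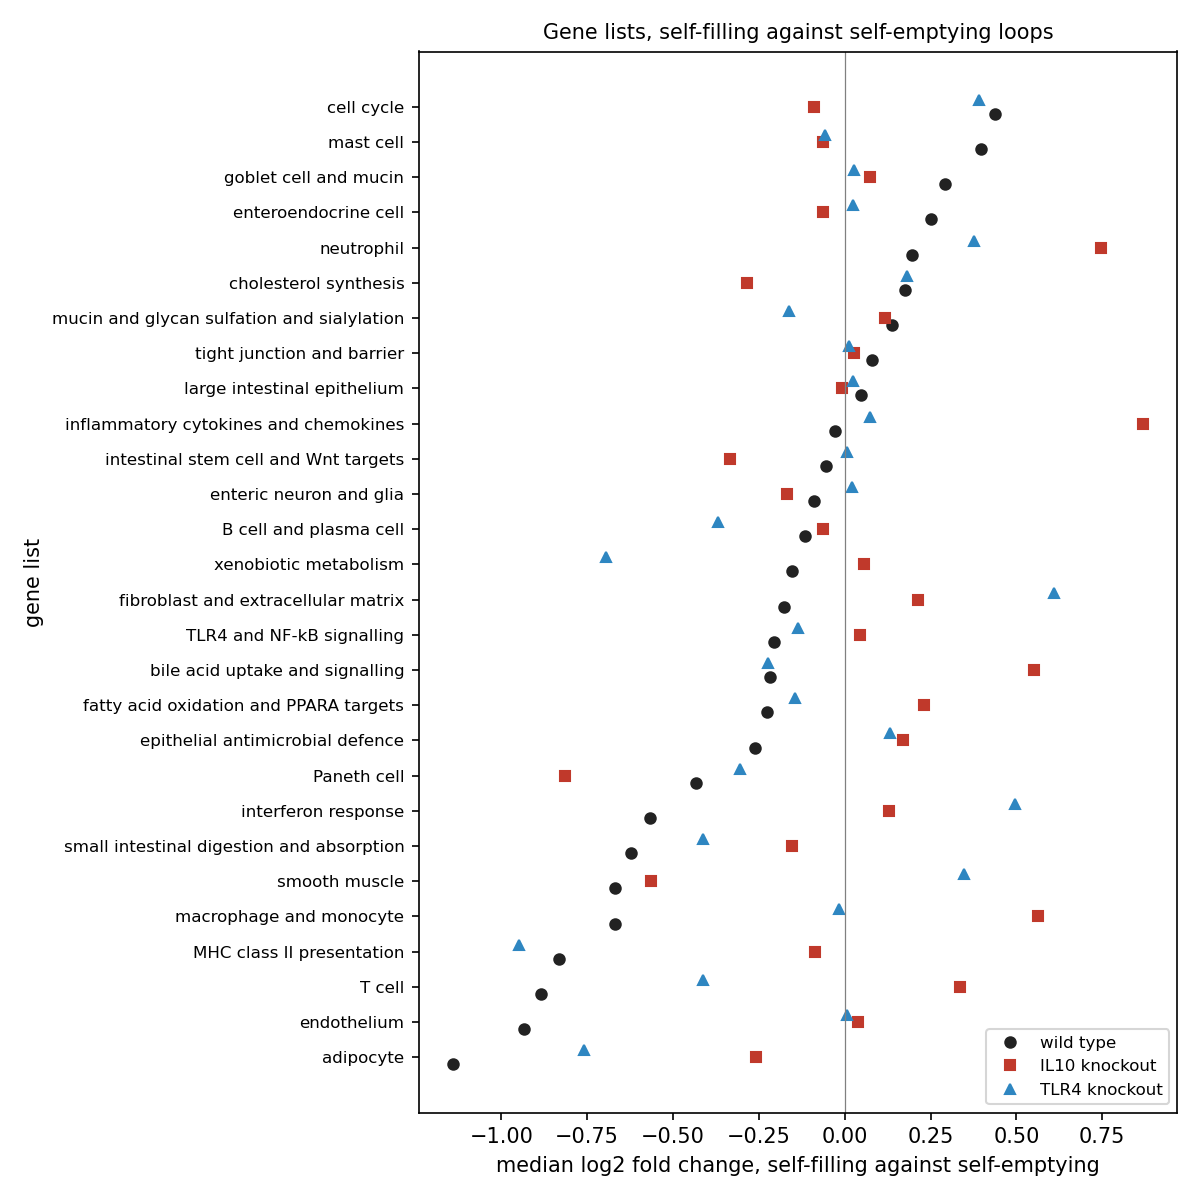
Median log2 fold change between self-filling and self-emptying loops of each gene list with at least 3 measured members (horizontal axis, log2 units), with 1 marker per genotype, by list (vertical axis). Adipocyte genes have the lowest median in wild type (-1.14), and inflammatory cytokines the highest in arrays labelled IL10 knockout (0.87).

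Whether the filling effect itself differs between genotypes was tested as an interaction. For loops labelled IL10 knockout against wild type 265 genes passed, 114 with a higher and 151 with a lower effect. The effect was higher for Lcn2 (4.36 ± 0.75, adjusted p = 0.00689), Hp (4.34 ± 1.01), Chil3 (4.00 ± 0.77), the alcohol dehydrogenase Adh1 (3.83 ± 0.59) and Cxcl10 (3.20 ± 0.50). It was lower for the transferrin receptor Tfrc (-2.51 ± 0.49), the retinol-binding Rbp7 (-2.52 ± 0.60), Myl7 (-2.85 ± 0.43), Phlda2 (-3.16 ± 0.68) and the unnamed locus LOC100045250 (-6.15 ± 1.51). Inflammatory cytokines differed upward in 4 of 18 cases (8 adjusted over the list alone), with Cxcl9 at 2.50 ± 0.62, Ifng at 1.97 ± 0.26 and Tnf at 1.80 ± 0.45. Interferon genes did so in 5 of 24, with Rsad2 at 2.29 ± 0.52 and Ifit2 at 2.29 ± 0.58, T cell genes in 2 of 11, with Cd3d at 2.29 ± 0.59, macrophage genes in 2 of 13, with C1qb at 2.52 ± 0.67, and TLR4 and NF-kB genes in 1 of 22, Nfkbia (2.07 ± 0.36). Cxcl9 and Cxcl10 count in both the cytokine and the interferon list. Rsad2 had fallen with filling in wild type loops, so a higher effect need not be a rise in the knockout. Endothelial genes differed upward in 1 of 10 and cholesterol synthesis genes downward in 2 of 14, and the MHC class II (0.65), fibroblast (0.46), adipocyte (1.02) and cell cycle (-0.69) medians shifted with no member past the test. Adjusted over the list alone, the numbers were 6 for interferon genes, 6 for T cells, 8 for macrophages, 5 for TLR4 and NF-kB, 2 for endothelium, 6 for cholesterol synthesis, 2 for MHC class II and 1 for the cell cycle. All 11 camera calls ended with an estimated correlation (adjusted p = 0.437 for MHC class II, adjusted p = 0.452 for the cell cycle, adjusted p = 0.546 for fibroblasts and adipocytes and adjusted p = 0.42 for the others). The fibroblast and adipocyte calls also ended with runs as a block (adjusted p = 0.0945 each), with the signal ratio as a covariate (adjusted p = 0.273 and adjusted p = 0.141) and without the 2 wild type arrays of codes 9 to 16 (adjusted p = 0.323 each). The count was 827 with array weights, and 411 with description numbers as a block. It was 16 without the 2 wild type self-emptying arrays of codes 9 to 16 and 94 with only these 4 groups in the fit. Single arrays moved it to 52, 84 and 515 (without wild type self-filling replicates 3, 1 and 2), 124 and 139 (self-emptying 2 and 3), and 103, 171, 149 and 131 (without IL10 knockout self-filling 1 and 2 and self-emptying 2 and 3).

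For TLR4 knockout against wild type limma found 0 genes whose filling effect differed, with 682 at an unadjusted p under 0.05. With array weights 7 passed, and 1 with the mean of a gene's probes or with description numbers as a block. Without TLR4 knockout self-filling replicate 2 there were 9, 2 without wild type self-filling replicate 1, and 1 without TLR4 knockout self-filling replicate 3 or wild type self-filling replicate 2 or 3. Interferon genes had a higher filling effect in TLR4 knockout loops as a list (median 0.91, camera adjusted p = 4.9e-16 with the preset correlation and adjusted p = 0.106 with an estimated one), with 10 of 24 members past the test adjusted over the list alone and 0 over all genes. Smooth muscle (1.10), endothelial (0.85), fibroblast (0.77), antimicrobial (0.53) and macrophage (0.50) medians were higher too, and the xenobiotic median was lower (-0.43), with 0 members past the test over all genes in limma and, adjusted over the list alone, 2 of 17 xenobiotic genes. The macrophage (adjusted p = 0.106) and xenobiotic lists (adjusted p = 0.281) lost their call without TLR4 knockout self-filling replicate 2. The macrophage call also ended with runs as a block (adjusted p = 0.214), with the signal ratio as a covariate (adjusted p = 0.575) and without the 2 wild type arrays of codes 9 to 16 (adjusted p = 0.695). None of these other lists held with an estimated correlation, where adjusted p = 0.336 for antimicrobial genes, adjusted p = 0.667 for macrophages and adjusted p = 0.625 for the rest.

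Between genotypes at equal surgery, self-filling loops labelled IL10 knockout were compared with those of wild type. S100a8 (6.12 ± 0.87, adjusted p = 7.88e-05), Lcn2 (5.87 ± 0.55, adjusted p = 5.53e-07), S100a9 (5.41 ± 0.73), Chil3 (4.99 ± 0.56, with 3.81 on its other probe), Fpr2 (4.67 ± 0.45) and Saa3 (3.95 ± 0.61) were higher. Gsdmc2 (-4.69 ± 0.99) and Arg2 (-3.77 ± 0.35) were lower, and Gsdmc3 was at least 11.6-fold lower. Interferon genes were higher in 14 of 24 cases (16 adjusted over the list alone), with the GTPases Igtp (4.2 ± 0.45) and Gbp2 (4.00 ± 0.47). Cytokines were higher in 12 of 18 (14 adjusted over the list alone), with Cxcl9 at 4.51 ± 0.46, Cxcl10 at least 11.3-fold, Il1b at 3.37 ± 0.76 and Ccl4 at 3.39 ± 0.42 (1.76 on its other probe). Both lists and the neutrophil list (4 of 8) held with an estimated correlation, at adjusted p = 0.0352 each, as did antimicrobial genes at adjusted p = 0.0493 (4 of 19 higher, 7 adjusted over the list alone, and 1 lower), among them the nitric oxide synthase Nos2 (2.08 ± 0.50).

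Further lists separated these loops only with the preset correlation. T cell genes were higher in 9 of 11 cases, with Cd3d at 2.62 ± 0.43 and Cd3g at 2.36 ± 0.47 (adjusted p = 0.121 with an estimated correlation), and macrophage genes in 9 of 13, with C1qb at 2.77 ± 0.49 and C1qc at 2.51 ± 0.47 (adjusted p = 0.138 with an estimated correlation). TLR4 and NF-kB genes were higher in 9 of 22 cases, with Tlr2 at 2.16 ± 0.19 and Nfkbia at 2.07 ± 0.27 (adjusted p = 0.0984 with an estimated correlation). MHC class II genes were higher in 7 of 12, with H2-Eb1 at 1.95 ± 0.35 and its regulator Ciita at 1.55 ± 0.34 (adjusted p = 0.2 with an estimated correlation). Enteroendocrine genes were lower in 9 of 12, with Nts at -1.45 ± 0.43, the serotonin enzyme Tph1 at -1.33 ± 0.30 and chromogranin Chga at -1.22 ± 0.27 (adjusted p = 0.205 with an estimated correlation). Barrier genes were lower in 4 of 13, with Ocln at -0.78 ± 0.22 and F11r at -0.70 ± 0.15 (adjusted p = 0.271 with an estimated correlation). Endothelial genes were higher in 5 of 10 and fibroblast genes in 1 of 18, and Paneth cell (6 of 13), fatty acid oxidation (3 of 13), cholesterol synthesis (3 of 14), xenobiotic (5 of 17) and digestive genes (4 of 23) were lower. With an estimated correlation adjusted p = 0.281 for endothelium, Paneth cells and fatty acid oxidation, adjusted p = 0.451 for fibroblasts, adjusted p = 0.294 for cholesterol, adjusted p = 0.377 for xenobiotic and adjusted p = 0.493 for digestive genes. Adjusted over the list alone, the numbers were 9 for T cells, 10 for macrophages, 11 for TLR4 and NF-kB, 7 for MHC class II, 10 for enteroendocrine cells, 4 for barrier genes, 6 for endothelium, 0 for fibroblasts, 7 for Paneth cells, 5 for fatty acid oxidation, 3 for cholesterol, 6 for xenobiotic and 4 for digestive genes. With runs as a block the xenobiotic (adjusted p = 0.0568) and barrier calls (adjusted p = 0.0552) ended, and with the signal ratio as a covariate those of digestive, cholesterol, xenobiotic and barrier genes (adjusted p = 0.0588 each). In all 1413 genes passed, 668 higher and 745 lower. The count was 778 and 892 without wild type self-filling replicates 1 and 3, 860 without IL10 knockout self-filling replicate 1 and 741 with only these 6 arrays in the fit.

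Self-emptying loops labelled IL10 knockout also differed from wild type, in 1072 genes, 588 higher and 484 lower. Lrg1 (4.26 ± 0.41, adjusted p = 7.36e-06), S100a8 (4.26 ± 0.81, adjusted p = 0.00266), Ly6d (4.22 ± 0.67) and Retnlb (3.93 ± 1.03) were higher, and S100a9 was at least 10.8-fold higher. Cyp2d26 (-4.33 ± 0.46), the retinol dehydrogenase Rdh7 (-3.80 ± 0.59) and the scaffold protein Pdzk1 (-3.35 ± 0.88) were lower. Interferon genes were higher in 10 of 24 cases, with Igtp at 2.66 ± 0.42, the antigen transporter Tap1 at 2.30 ± 0.31 and Psmb9 at 2.02 ± 0.22 (adjusted p = 0.232 with an estimated correlation). Neutrophil genes were higher in 5 of 8 (adjusted p = 0.117 with an estimated correlation), and cell cycle genes in 7 of 20, with Aurka at 1.10 ± 0.23, Plk1 at 1.04 ± 0.24 and Top2a at 1.01 ± 0.28 (adjusted p = 0.392 with an estimated correlation). Cytokines were higher in 4 of 18 (adjusted p = 0.466 with an estimated correlation). Xenobiotic genes were lower in 7 of 17, among them the epoxide hydrolase Ephx2 (-2.13 ± 0.41) (adjusted p = 0.137 with an estimated correlation), and fatty acid oxidation genes in 5 of 13, with Acaa2 at -1.60 ± 0.25 and Ehhadh at -0.79 ± 0.20 (adjusted p = 0.117 with an estimated correlation). Digestive genes were lower in 4 of 23 and enteroendocrine genes in 2 of 12, and the adipocyte median was -1.01 with no member past the test (adjusted p = 0.466, adjusted p = 0.518 and adjusted p = 0.518 with an estimated correlation). The numbers were, adjusted over the list alone, 12 for interferon, 5 for neutrophils, 15 for the cell cycle, 5 for cytokines, 11 for xenobiotic, 9 for fatty acid oxidation, 7 for digestive and 4 for enteroendocrine genes. The mucosal defence genes Dmbt1 (1.45 ± 0.20) and Duox2 (1.14 ± 0.26) were higher. The genes called in both loop types overlapped in 134 higher and 159 lower genes, against 35 and 32.1 for independent lists. The adipocyte call ended without the 2 wild type arrays of codes 9 to 16 (adjusted p = 0.381). The count was 2034 with array weights. It was 260 without the 2 wild type arrays of codes 9 to 16, 542 without wild type self-emptying replicate 2, 459 and 557 without IL10 knockout self-emptying replicates 1 and 3, and 589 with only these groups in the fit.

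TLR4 knockout loops differed from wild type loops in 1273 genes with filling (536 higher, 737 lower) and in 633 with emptying (232 higher, 401 lower). All 6 TLR4 knockout arrays carried codes of another series than the other 19 arrays, so genotype and array set cannot be told apart in these numbers. Probe sequences were not at hand, so a strain variant under a probe, which changes hybridisation and not expression, was not excluded for any gene named here. The cell cycle inhibitor Cdkn2b was lowest in both, by -4.08 ± 0.15 (adjusted p = 7.97e-14) in self-filling and -4.33 ± 0.14 (adjusted p = 5.99e-15) in self-emptying loops. Gpn2 (-2.48 ± 0.17 and -2.02 ± 0.16) and Bsdc1 (-2.16 ± 0.16 and -2.54 ± 0.15) were lower in both, as was the Paneth cell protease Mmp7 (-1.51 ± 0.21 and -1.62 ± 0.20). With filling, thioredoxin Txn1 changed by -2.16 ± 0.22, but by -0.19 on its other probe, and Tom1l2 was at least 3.35-fold lower, while its other probes gave 0.07 and 0.42. The calls of both loop types overlapped in 83 higher and 298 lower genes, against 11.1 and 26.3 for independent lists.

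In self-filling loops interferon genes were higher in 10 of 24 cases in TLR4 knockout than in wild type arrays (13 adjusted over the list alone), with Rsad2 at 2.80 ± 0.38, the interferon regulator Usp18 at 2.54 ± 0.47, Isg15 at 2.46 ± 0.44 and Ifit3 at 2.43 ± 0.61. Smooth muscle genes were higher in 6 of 14, with Myh11 at 2.19 ± 0.61 and Smtn at 1.71 ± 0.45, and endothelial genes in 5 of 10, with Cldn5 at 1.65 ± 0.38 and Plvap at 1.58 ± 0.33. Fibroblast genes were higher in 2 of 18. Barrier genes were lower in 5 of 13, with Tjp1 at -1.05 ± 0.22, and Agr2 was lower (-1.93 ± 0.30). The numbers adjusted over the list alone were 12 for smooth muscle, 7 for endothelium, 4 for fibroblasts and 5 for barrier genes. Without self-filling replicate 2 of the knockout the fibroblast (adjusted p = 0.235) and barrier lists (adjusted p = 0.0584) were no longer called, nor was the fibroblast list with the signal ratio as a covariate (adjusted p = 0.686). With an estimated correlation adjusted p = 0.8 for interferon, smooth muscle and endothelium, adjusted p = 0.917 for fibroblasts and adjusted p = 0.471 for barrier genes. In self-emptying loops the xenobiotic enzyme Cyp2c55 (2.80 ± 0.52), the glucose transporter Slc2a2 (2.38 ± 0.40, with 1.28 on its other probe) and 1700057G04Rik (2.0 ± 0.27) were higher, and Cfap57 was at least 3.05-fold higher. H2-Aa (-2.08 ± 0.35) and the protease Ctss (-1.19 ± 0.17), 2 of 3 lower genes among 12 of the MHC class II list, Tmigd1 (-1.97 ± 0.35) and the complement factor Cfb (-1.14 ± 0.17) were lower. Antimicrobial genes were lower in 2 of 19 and barrier genes in 3 of 13, and adjusted over the list alone 5 MHC class II, 3 antimicrobial and 4 barrier genes were lower. With an estimated correlation adjusted p = 0.89 for MHC class II and adjusted p = 0.368 for the other lists. Without the 2 wild type arrays of codes 9 to 16 the antimicrobial (adjusted p = 0.0934) and MHC class II calls (adjusted p = 0.152) ended, the latter also without background correction (adjusted p = 0.0614). The count with filling was 2626 with array weights and 440 with the signal ratio as a covariate. It was 555, 584, 578 and 833 without wild type self-filling replicates 3 and 1 and TLR4 knockout self-filling replicates 1 and 3. That with emptying was 346 without wild type self-emptying replicate 4 and 393 and 365 without TLR4 knockout self-emptying replicates 2 and 3. With only the compared groups in the fit they were 758 and 170.

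**Figure D3:**
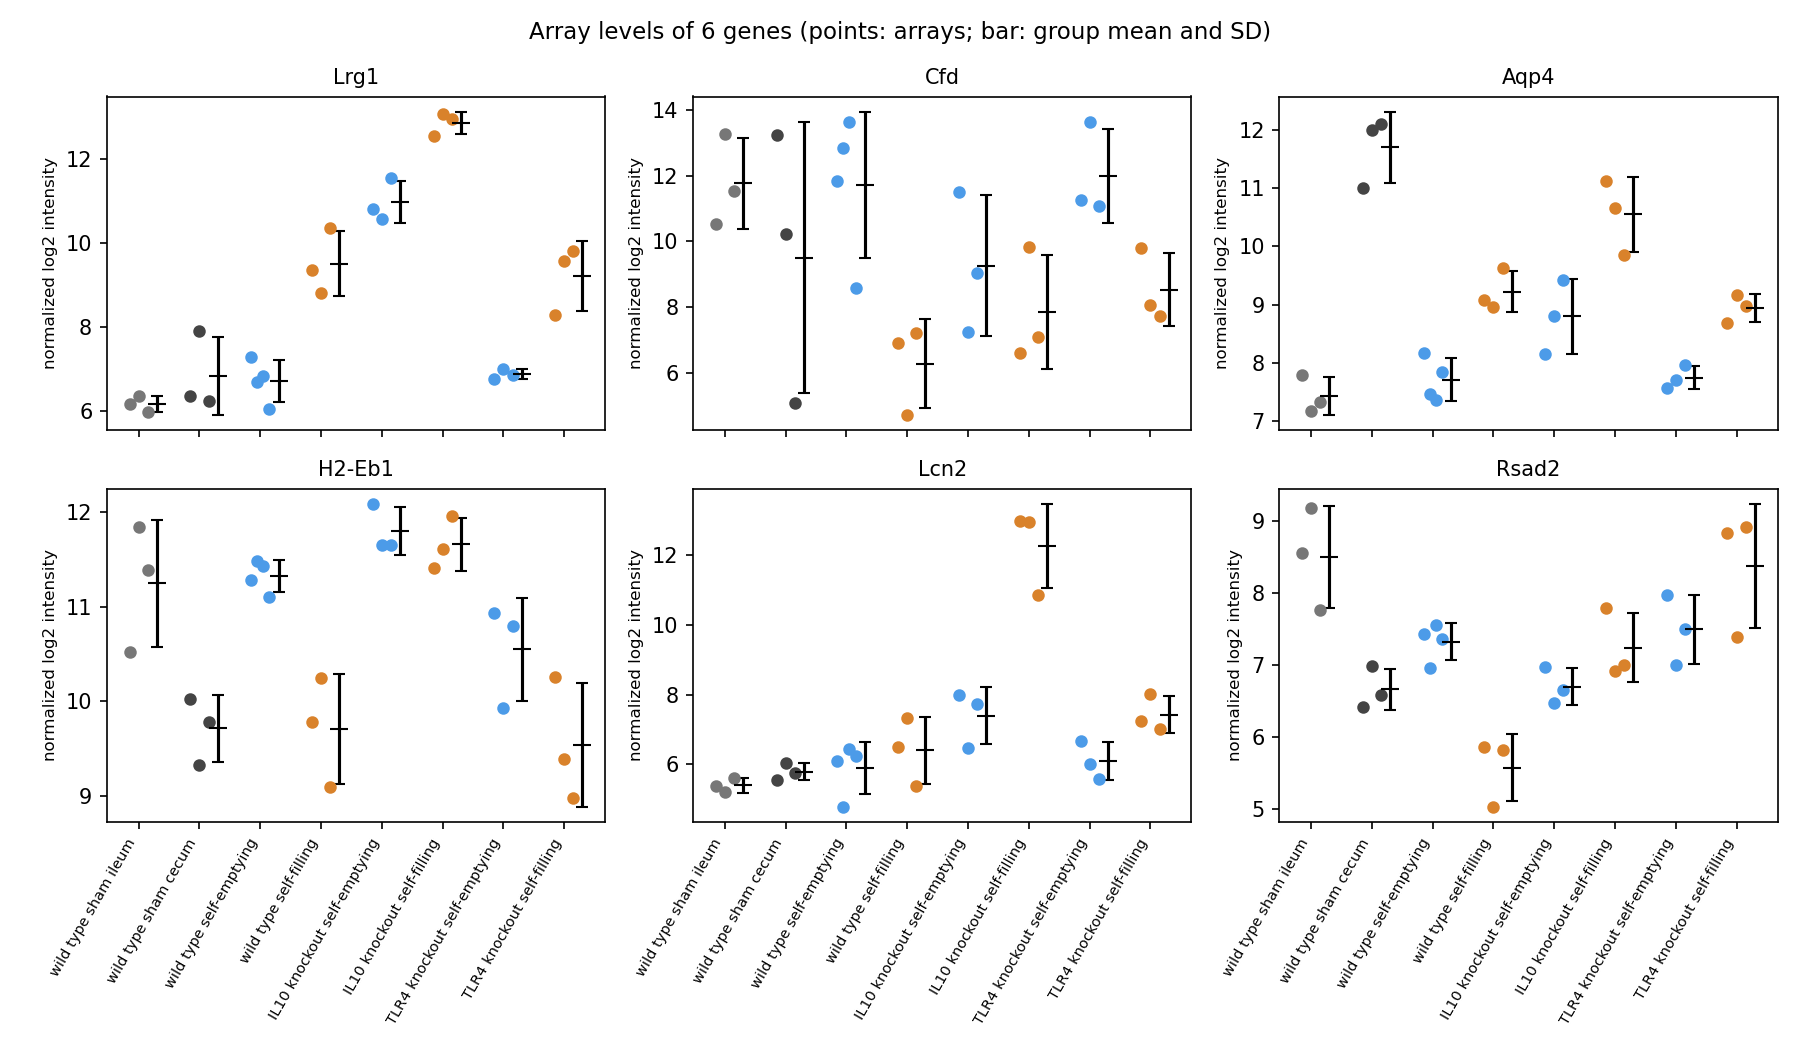
Normalized log2 intensity (vertical axes) of 6 genes on each array, by group (horizontal axes). Points are arrays, and the bars at their right are the group mean and SD. Lrg1 and Aqp4 are higher, and Cfd and H2-Eb1 lower, in wild type self-filling than in self-emptying loops, and Lcn2 is highest in self-filling loops labelled IL10 knockout.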

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

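The counts by other splits of the arrays, the block on runs of codes and the fit with the signal ratio as a covariate were tests chosen only after the results were seen, the last with its bounds set when its values were known, and the test on the axis of loops labelled IL10 knockout was written down before its value was known. The interaction test found 265 genes whose filling effect differed between arrays labelled IL10 knockout and wild type. The named ones, as knockout minus wild type log2 effects, were Lcn2 (4.36), Hp (4.34), Chil3 (4.0), Adh1 (3.83), Cxcl10 (3.20), C1qb (2.52), Cxcl9 (2.50), Rsad2 (2.29), Ifit2 (2.29), Cd3d (2.29), Nfkbia (2.07), Ifng (1.97), Tnf (1.80), Tfrc (-2.51), Rbp7 (-2.52), Myl7 (-2.85), Phlda2 (-3.16) and LOC100045250 (-6.15). Exchanging loop labels would also remove the filling effect that both genotypes share, so this was taken off first. Of 100 drawn splits 2, the real one included, then gave as many genes, a share under 0.05. This argues against chance alone, but the share was not adjusted over the comparisons tested by splits. The other of these 2 splits gave 375, more than the real one, with the loop labels of 4 arrays exchanged in each genotype. With the shared effect left in, 2 splits again gave as many and the highest other gave 614, but that form does not test whether the effects are equal.

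Of 105 values examined in the 4 wild type self-emptying arrays, 4 had an array far from the rest, and chance gives about 1 in 20. Akr1b8 was 5.17 on replicate 2 against 6.02 to 6.18 on the others, a gap of 0.838 of the range. Cd3g was 8.33 on replicate 2 against 7.66 to 7.73 (0.895). LOC100045250 was 11.8 on replicate 3 against 8.18 to 8.44 (0.928), and Phlda2 was 6.06 on replicate 3 against 4.82 to 5.0 (0.859). These are the 2 arrays of codes 9 to 16 in that group.

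Between wild type self-filling and self-emptying loops 1295 genes passed. On an axis made from the loops labelled IL10 knockout, the gap within the runs with both loop types was 0.21 (3 against 2 arrays, SDs 0.103 and 0.0765). It was 0.219 over all wild type loop arrays. This argues against the array run as the whole cause of the shift on that axis. So few arrays allow no permutation p under 0.05, and the gap does not show how many of the 1295 calls the run explains. The fit with the signal ratio as a covariate argues against a linear effect of signal spread as the whole cause of the count. Its bounds were set when its values were known, so it is no independent test. In that fit 329 genes passed in the real split and at most 10 in the others, among them the split that gave 664 without the covariate. The other splits mix the loop types, so their counts do not measure signal spread alone. The 1295 genes had fold changes with a slope of 0.846 on those without the covariate and a median SE of 0.2 after 0.186 before, and 288 of them passed, so the other calls ended with smaller changes and larger errors. Run and signal spread may each have added to the count, as the ratio differs between the groups (15.7 ± 0.499 (SD, n = 3) with filling, 12.3 ± 2.84 (SD, n = 4) with emptying), and stasis stays open beside them.

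Over the 35 splits of the wild type loop arrays the real count of 1295 was reached by 1 split, the real one, and the highest other gave 664. This argues against chance alone, with a share that was not adjusted over the comparisons tested by splits. That split set self-emptying replicates 2, 3 and 4 against the rest, and with runs of codes as a block the real count was 714. The same held for self-emptying loops labelled IL10 knockout against wild type (1072, highest other 273, 1 of 35) and for TLR4 knockout against wild type self-emptying loops (633, highest other 128, 1 of 35). For self-emptying loops against sham ileum chance could not be excluded, since 4 of 35 splits gave at least the real count of 1. The highest other, 60, parted the arrays of codes 9 to 16 from the rest, and the count was 1 with runs as a block. For the TLR4 interaction limma gave 0 genes (682 at an unadjusted p under 0.05), a count that all 100 splits reach whatever the labels, so the splits say nothing of it. The highest other was 38 with the shared filling effect taken off and 490 with it left in. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 2212 and 1 for self-filling loops against sham ileum, 3121 and 0 for cecum against ileum, 462 and 3 and 9 and 1 for filling against emptying in loops labelled IL10 knockout and TLR4 knockout, and 1413 and 9 and 1273 and 40 for loops with these labels against wild type self-filling loops.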

How the results depend on the processing

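The tests with runs of codes as a block, with the signal ratio as a covariate, without the 2 wild type self-emptying arrays of codes 9 to 16 and, for lists, without TLR4 knockout self-filling replicate 2 were chosen after seeing the data, and the others were planned. IL10 knockout stands for arrays with that label. Of 243 named gene results under all alternatives (5027 values), 4394 kept direction and side of the threshold, 629 kept direction but no longer passed, 4 passed anew and 0 reversed. Many of these genes were named because they passed without overlap between the groups, which leaves little room for reversals. The authors' values are nearly the present normalization and so are a weak alternative. Of 104 list calls, 101 held without background correction, 104 with the authors' values, 44 in fry and 8 with an estimated correlation, 89 of 96 with the block on runs, 89 of 104 with the covariate, 35 of 44 without the 2 arrays of codes 9 to 16 and 13 of 23 without TLR4 knockout self-filling replicate 2, and 0 reversed. In limma, counts moved by over 1.5 times as follows, and the cause was not tested unless fewer arrays or a stricter threshold is itself the change. With at least 1 log2 unit required, 584 genes passed between wild type self-filling loops and sham ileum, 352 between wild type loops, 1190 between cecum and ileum, 183 between IL10 knockout loops, 164 in the IL10 interaction, 559 and 283 between IL10 knockout and wild type in self-filling and self-emptying loops, and 313 and 103 between TLR4 knockout and wild type there. With array weights these were 3610 for self-filling loops and 25 for self-emptying loops against sham ileum, 2125 between wild type loops, 19 between TLR4 knockout loops, 7 and 827 in the TLR4 and IL10 interactions, 2034 for IL10 knockout self-emptying and 2626 for TLR4 knockout self-filling loops against wild type. With only the compared groups in the fit they were 9 for self-emptying loops against sham ileum, 5 and 0 for filling in IL10 and TLR4 knockout loops (9 genes in limma with all groups), 94 in the IL10 interaction, 741 and 589 for IL10 knockout against wild type and 758 and 170 for TLR4 knockout against wild type. The small counts for self-emptying loops against sham ileum and for filling in TLR4 knockout loops were 4 (1 higher, 3 lower) and 15 (5 higher, 10 lower) without background correction and 3 and 14 with normexp at an offset of 50. The first was also 2 without a detection filter and 4 with a trended and robust prior, and the second 14 with detection at p under 0.01 on every array of a group. With the mean of a gene's probes 1 gene passed in the TLR4 interaction. The covariate gave 329 between wild type loops and 440 between TLR4 knockout and wild type self-filling loops, and the block on runs 714 between wild type loops. Without the 2 arrays of codes 9 to 16 the counts were 3 for self-emptying loops against sham ileum, 86 between wild type loops, 16 in the IL10 interaction and 260 and 373 for IL10 and TLR4 knockout against wild type self-emptying loops. Over genes called between cecum and ileum alone, the filling effect correlated with that difference with r of 0.328 in wild type, 0.259 in IL10 knockout and 0.355 in TLR4 knockout loops.

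Replicate numbers of the titles showed no pairing of the samples. Deviations of same-numbered arrays had a median correlation of -0.0116 over 48 pairs, 12 of them over 0.1. By description number it was 0.0428 over 44 pairs, 17 of them over 0.1, against -0.0326 and 32 of 115 for different numbers. For filling in IL10 knockout loops the 3 pairs lay at 0.0506 to 0.294 by description and at -0.244 to -0.0576 by title. In no comparison were all pairs over 0.1, and pairing by description number stays open. With the replicate block from the titles 2 genes passed for self-emptying loops against sham ileum and 32 for filling in TLR4 knockout loops. With the block by description number these were 4 and 30, with 1 in the TLR4 and 411 in the IL10 interaction. Blocks were not fitted for TLR4 knockout against wild type, and the slide as a block was not run, since no slide is given.

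Leaving out each array in turn gave 905 to 1972 genes for self-filling loops and 0 to 2 for self-emptying loops against sham ileum, 356 to 1414 between wild type loops, 104 to 759 and 0 to 37 for filling in IL10 and TLR4 knockout loops, 0 to 9 in the TLR4 and 52 to 515 in the IL10 interaction, 778 to 1394 and 459 to 986 for IL10 knockout, and 555 to 1377 and 346 to 535 for TLR4 knockout against wild type in self-filling and self-emptying loops. The wild type shift toward cecum ranged from 0.0865 to 0.116, and its exact permutation p of 0.0667 or 0.1 was then the smallest possible where a wild type loop array was missing. The share of probes detected over background, 47.2 to 53.0% per array, limits what can be read of dim genes.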

Other observations

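The wild type response position was a test chosen only after the results were seen, and the tests of fat and of chromosomes were written down before their values were known. Arrays were placed between mean wild type self-emptying (0) and self-filling loops (1) over genes called between these with at least 1 log2 unit. Loops labelled IL10 knockout lay at 0.534 ± 0.13 (SD, n = 3) with emptying and 0.83 ± 0.128 (SD, n = 3) with filling, and TLR4 knockout loops at 0.0856 ± 0.0397 (SD, n = 3) and 0.558 ± 0.263 (SD, n = 3). Wild type loop arrays, each left out of its own scale, lay at 0.131 ± 0.217 (SD, n = 4) and 0.805 ± 0.164 (SD, n = 3). The differences of 0.296 and 0.472 in the knockouts each had p = 0.1 in the exact two-sided permutation test, the smallest it can give. Sham cecum lay at 0.468 ± 0.0795 (SD, n = 3). Between the filling effects in wild type loops and in loops labelled IL10 knockout 37 rises and 40 falls were shared, against 12.8 and 13.8 for independent lists, and 2 and 3 genes passed in opposite directions.

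Some fixed lists passed camera in no comparison. B and plasma cell genes had none of 12 members past the test between wild type loops, also adjusted over the list alone (median -0.12, camera adjusted p = 0.382). Mast cell genes rose in 1 of 6 cases (median 0.40, camera adjusted p = 0.241) and genes of enteric neurons and glia fell in 2 of 11 (median -0.09, camera adjusted p = 0.225), with the same numbers adjusted over the list alone. Of the pancreatic acinar list 2 genes were measured, too few for a set test. In self-filling loops against sham ileum Cela1 rose (1.75 ± 0.21, adjusted p = 6.27e-05) and Pnliprp1 was at -0.85 (adjusted p = 0.379).

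The mean of the adipocyte list was lower in wild type self-filling loops, at 5.60 ± 0.235 (SD, n = 3). It was 7.56 ± 1.1 (SD, n = 4) in self-emptying loops and 7.60 ± 0.972 (SD, n = 3) in sham ileum. The most abundant members Cfd and Adipoq lay at 6.28 and 5.02 against 11.72 and 8.87 in self-emptying loops. Between these loops Cfd passed and Adipoq did not. The camera call of the list between the loops ended with an estimated correlation and with the signal ratio as a covariate. That call also ended without the wild type self-emptying arrays of codes 9 to 16. The 3 of 3 self-filling arrays lay below all 7 others. By the rule written down beforehand this counts against a few arrays with much fat as the cause. The margin was only 0.361 (at most 5.75 against at least 6.11), less than the largest group SD, a condition that was not in that rule. A few arrays with much fat therefore stay open as a cause. Within groups the 7 measured members, 0 of them in another list, moved together, with a mean pairwise correlation of 0.611, against 0.00289 for random lists of that size. Different amounts of fat on the sampled pieces may contribute. Random lists are not markers of a single cell type, though, and variation within groups does not tell what set the groups apart. A change of the tissue with stasis stays open and was not tested.

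Of 59 genes that differed by at least 1 log2 unit between TLR4 knockout and wild type arrays in both loops, 14 of the 53 with a known chromosome lay on that of Tlr4, 26.4% against 6.15% of tested genes (Fisher's exact p = 2.46e-06). Without the genes named above the share was 22.7% of 44 (Fisher's exact p = 0.000249), which the array set as its cause would not give. DNA linked to Tlr4 that differs between the strains is a candidate explanation, but the share of such genes was 3.5% among the 200 nearest tested genes and 1.48% on the rest of the chromosome (Fisher's exact p = 0.135), which leaves it open. Such variants may act on expression or on hybridisation to a probe, and Txn1, on this chromosome, was at -2.16 on its main probe and -0.19 on its other probe in self-filling loops. The 39 genes on other chromosomes may follow genotype or array set, and these cannot be told apart because every TLR4 knockout array is in 1 set.

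Of 116 genes that differed by at least 1 log2 unit between arrays labelled IL10 knockout and wild type in both loops, 9 lay on the chromosome of Il10, 7.76% against 5.33% of tested genes. Il10 itself is counted among the 116 and the 9. The test was made without it (Fisher's exact p = 0.401).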
